A study of Mus musculus with 5 samples.

How the data were processed

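Single cells from sham-operated mouse cortex and from cortex 1, 3, 7 and 14 days after traumatic brain injury were profiled with the 10x Genomics 3′ v3 chemistry, 1 library per group, all from C57BL/6J mice. Per the labels' protocols, the tissue was dissociated with papain and DNase, debris was removed on a Percoll gradient, and the libraries were sequenced in pairs of 150 bp on an Illumina HiSeq. Each library came as a matrix of genes by barcodes. Per the file headers, the authors made these UMI counts with Cell Ranger 4.0.0, and they are deposited as whole numbers with no normalization. The submitters' processing notes also name STAR 2.5.37 and Seurat 3.2.0, and the builds GRCm38 and mm10, without saying which step each served. What Seurat was used for is not given in the sources used here, and no cell annotation was used. All 55450 gene IDs of the matrices were found in GENCODE mouse release 21, which gave the gene positions on GRCm38. 108 symbols are shared by several IDs, and such genes were kept apart by ID.

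The lowest total per barcode was between 499 and 502 UMIs in the 5 libraries, so the barcodes had already been called as cells. Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. Doublets were called in each library with Scrublet as implemented in scanpy, at its automatic threshold, which marked 11.1%, 7.82%, 5.23%, 4.65% and 3.82% of barcodes from sham to day 14, and were removed. In all, 54585 of 60574 barcodes were kept.

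Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes gave 30 principal components, 15 nearest neighbours per cell and Leiden clusters at resolution 1. No batch correction was used, because each group is 1 library. The 35 clusters were named from 257 marker genes of 17 classes fixed before the data were examined. A marker counted for a cluster when at least 10% of its cells had a UMI and its level was at least 2-fold that of the reference, with 10 CPM added to both. A name needed at least 3 such markers and could not go against the 10 genes with the highest fold, and 33 clusters were named. Clusters named in a first pass then served as the reference of other classes in a second pass. That second pass was chosen after a first ranking against all other cells had left 3 more clusters unnamed, and naming against all other cells is kept as an alternative. Names stand for likeness to markers, and the 2 unnamed clusters entered no class.

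The microglia/macrophage class joined the microglia-like and monocyte/macrophage-like clusters. UMIs were summed over the cells of a class in each library and divided by the class total to give CPM. The microglia/macrophage totals were 3669425, 8187553, 17273568, 49411577 and 69681700 UMIs from sham to day 14, so that 1 UMI was worth 0.273 CPM in sham and 0.0144 CPM at day 14. Each injured library was set against sham as a log2 ratio of CPM. With 1 library per group no test was run and no count of changed genes was made from cells. Sums have exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95%, and they cover counting error only. For a class with 0 cells the limit given is 3 cells of the library's total, in place of the exact interval. A gene with 0 sham UMIs was set against a floor of 3 UMIs, and its ratio is a lower bound. Classes were compared where both libraries held at least 50 cells. For shares of cells with a UMI, each cell was thinned at random to 500 UMIs, which left out none of the kept cells.

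Gene lists fixed before the data were examined numbered 24 and held 321 genes. In microglia/macrophages these were m6A erasers, writers and readers, the SOCS family, JAK-STAT and gp130 receptors, homeostatic microglia, inflammatory cytokines and NF-kB, alternative activation, disease-associated microglia, interferon response, MHC class II, cell cycle, complement, cholesterol efflux and lipid storage, cholesterol synthesis, glycolysis, and immediate early and heat shock genes. Lists of reactive and homeostatic astrocyte genes, of endothelial adhesion, tip cell and blood-brain barrier genes, and of myelin and oligodendrocyte injury genes were read in their own class, together with the m6A and SOCS lists. All genes of the myelin list, and most of the homeostatic microglia and astrocyte lists, were also markers used to name clusters. Cells that lost them could fall out of the class, so these lists were read in cells partly chosen for their genes. A member was measured when its mean CPM over the 2 libraries was at least 10. The median log2 ratio over measured members was placed among 10000 random lists of the same size, drawn from 20 bins of mean CPM, and its percentile only describes these libraries. Intervals of list medians came from 500 Poisson resamples.

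The genes to name were also set by rule before the data were examined. Of genes with at least 50 CPM in 1 of the 2 libraries, the 12 with the highest lower bound of the log2 ratio and the 8 with the lowest upper bound were named for each injured library. Mitochondrial, ribosomal protein and haemoglobin genes, markers of other classes, and genes over 5 times higher in another class (free RNA) were left out. Genes up to 5 times higher in another class were kept, so a named gene need not be highest in microglia/macrophages and free RNA is not excluded for it. From each list up to 4 members with the bound farthest from 0 were named, and Alkbh5, Socs3, Fto, Mettl3, Mettl14 and Stat3 always.

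Simulated data with known answers were run through the same code. Of 1600 simulated cells of 8 classes at sham depth, 99.9% were named rightly. Each was drawn from the mean profile of a class named by the same markers, without doublets or library differences. This checks the code and cannot show how well the real clusters were named. Among 8737 genes simulated for each comparison, the intervals covered the true ratio of between 95.2% and 95.4% of unchanged genes and of at least 92% of genes changed by a known fold. A list simulated at 2-fold in the day 1 comparison lay at percentile 100, and 24 unchanged lists between 7.22 and 92.5. These counts were drawn from the sham profile with Poisson error alone and, for lists, with no other gene changed. The simulated intervals and percentiles thus also check the code only, and cannot show how either behaves between real libraries.

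Alternatives fixed beforehand were a minimum of 1000 UMIs, at most 10% mitochondrial UMIs, no doublet removal, Leiden resolution 2, naming each cell by its own marker score, TMM factors from edgeR, the mean over cells in place of the sum, microglia-like clusters alone, a measured minimum of 50 CPM, and other thinning depths. Alternatives added after the data were seen were naming against all other cells, the day 1 library in place of sham, microglia/macrophage shares without the erythrocyte, choroid plexus, ependymal and neuroblast classes, list medians over the members measured in the main setting, and a reweighting of sham cells by their UMIs from the 19 immediate early and heat shock genes at 500 UMIs per cell, with 500 resamples. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.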

Results

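Cortex from C57BL/6J mice was dissociated and profiled by droplet single-cell RNA sequencing in 5 libraries, 1 each from sham-operated mice and from mice 1, 3, 7 and 14 days after traumatic brain injury (TBI). The sample titles name the injury site for the injured libraries and no site for sham. Each library held counts of unique molecular identifiers (UMIs) for 55450 genes. The number of mice behind a library is not given in the sources used here, and no group had a second library, so there was no replicate and no test. Every interval gives the 95% range from counting error alone, and each comparison describes libraries rather than conditions.

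Depth differed widely and in the order of the time points. The sham library held 11279455 UMIs over 11571 barcodes, with a median of 773 UMIs per barcode. The day 1, 3, 7 and 14 libraries held 26705021, 41090570, 110205126 and 129161094 UMIs over 12724, 9895, 14159 and 12225 barcodes. Their medians were 1756, 3256, 6581 and 8558 UMIs per barcode, and 70.0% of sham barcodes lay under 1000 UMIs against 2.67% at day 14. The labels give about 5188 to 11934 cells loaded per sample, while the files hold between 9895 and 14159 barcodes. After filters and removal of called doublets, 10244, 11713, 9359, 11788 and 11481 cells were kept from sham to day 14. At day 7, 12.7% of barcodes had over 20% mitochondrial UMIs, against 0% in sham.

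The first comparison asked which cells made up the sham and injured libraries. Cells with markers of blood immune cells took larger shares in the injured libraries than in sham, and astrocyte-like cells a smaller share at days 7 and 14. Monocyte/macrophage-like cells made up 0.195% of sham cells (exact binomial interval 0.119 to 0.301) and 0.623%, 10.1%, 3.45% and 10.7% at days 1, 3, 7 and 14. Neutrophil-like cells, the early phagocytes of blood, stood at 0.0390% in sham and 3.99% (3.60 to 4.40) at day 3. T or NK cell-like cells, the lymphocytes of cellular immunity, stood at 0.166% (0.0967 to 0.266) in sham and 16.1% (15.4 to 16.7) at day 14. Dendritic cell-like cells were 0 of 10244 in sham, which allows a share of up to 0.0293%, and 1.72% at day 14.

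Microglia-like cells, the resident phagocytes of the brain, made up 43.5% of sham cells and 34.0%, 31.0%, 45.5% and 38.6% at days 1, 3, 7 and 14. Together with the monocyte/macrophage-like cells they formed a class of 43.7% (42.7 to 44.6) in sham and 34.6%, 41.1%, 49.0% and 49.4% in the injured libraries. Within that class the monocyte/macrophage-like part was 0.447% in sham, 24.6% (23.3 to 26.0) at day 3 and 21.8% (20.7 to 22.9) at day 14. Astrocyte-like cells made up 39.8% of sham cells (38.9 to 40.8), then 38.8%, 22.8%, 15.2% and 2.39% (2.12 to 2.68) at days 1, 3, 7 and 14. Oligodendrocyte-like cells stood at 11.96%, 10.9%, 4.11%, 14.9% and 17.8% from sham to day 14. Oligodendrocyte precursor-like cells reached 4.83% at day 3 against 0.537% in sham, and neural progenitor or neuroblast-like cells 17.4% against 3.03%. Endothelial-like cells reached 3.16% at day 7 against 0.742% in sham.

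Because the sample titles name the injury site for the injured libraries only, a difference in the tissue taken cannot be told apart from injury in such shares. Dissociation and depth can also set them, and several moved by more than 1.5 times under another filter. Requiring 1000 UMIs per cell gave sham shares of 20.4% for astrocyte-like, 40.03% for oligodendrocyte-like and 1.36% for endothelial-like cells, and neutrophil-like shares of 0.450% at day 1 and 1.87% at day 3. With that filter the astrocyte-like shares at days 1 and 3, 38.5% and 23.6%, lay above sham, and the oligodendrocyte-like shares at days 7 and 14, 16.1% and 17.9%, lay below it. The T or NK share at day 1 was then 0.166%, below 0.233% in sham. The microglia/macrophage share was then 30.8% in sham against 36.8% at day 1 and 44.4% at day 3, above sham in place of below. The day 3 share of that class also lay above sham with doublets kept (39.8% against 38.7%) and without the classes scarce in sham (51.0% against 45.0%), and the day 14 share lay below it, at 40.8% against 43.7%, when clusters were named against all other cells. The astrocyte-like share was 7.18% at day 7 when at most 10% mitochondrial UMIs were allowed. It was 14.1% at day 3 under the same other naming, and scoring single cells by their markers gave 0.185% neutrophil-like cells in sham.

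**Figure D1:**
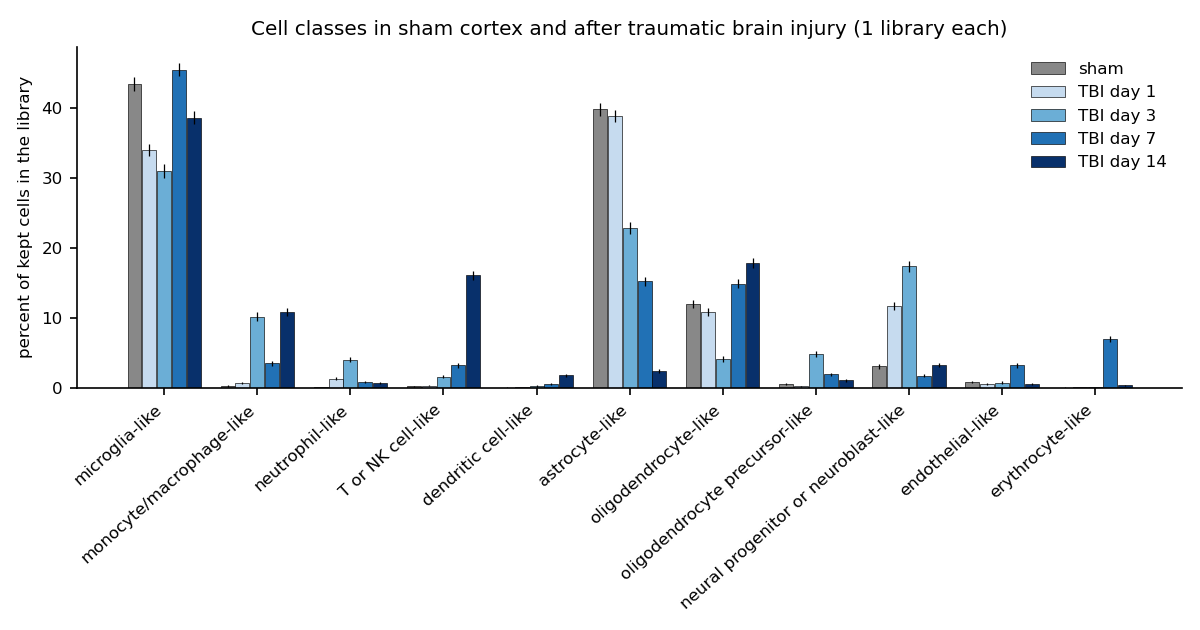
Percent of kept cells (vertical axis) in 11 cell classes (horizontal axis) for the sham library and the libraries at 1, 3, 7 and 14 days after TBI, with exact 95% binomial intervals that cover counting error only. T or NK cell-like cells reach 16.1% at day 14 and astrocyte-like cells 2.39%, while small classes and unnamed cells are not drawn.

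The series centres on ALKBH5, an enzyme that removes N6-methyladenosine (m6A) from RNA, and on SOCS3, which restrains cytokine signalling through JAK and STAT3. The next comparison asked how their RNA levels in microglia/macrophages differed between sham and injured cortex. These libraries do not measure m6A itself. Socs3 was slightly higher at day 1 than in the sham library and 2.88-fold lower at day 14. Alkbh5 was slightly higher at day 3 than in sham and 1.54-fold lower at day 14, where the median of all measured genes of the class was lower too.

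Alkbh5 (ENSMUSG00000042650) is a protein-coding gene on chromosome 11 of GRCm38, at 60536381 to 60558512 on the plus strand. It stood at 98.4 CPM (counts-per-million, exact Poisson interval 88.5 to 109) in sham microglia/macrophages, from 361 UMIs. In the injured libraries it stood at 103 (95.8 to 110), 118 (113 to 123), 72.3 (70.0 to 74.7) and 63.8 (62.0 to 65.8) CPM, from 840, 2038, 3573 and 4449 UMIs. The log2 ratios to sham were 0.06 (-0.12 to 0.24) at day 1, 0.26 (0.10 to 0.43) at day 3, -0.44 (-0.60 to -0.28) at day 7 and -0.62 (-0.78 to -0.47) at day 14. Across all measured genes of the class, between 8340 and 8743 per comparison, the median log2 ratio was itself -0.07, -0.36, -0.38 and -0.56. Relative to that median, Alkbh5 stood at 0.13, 0.63 (0.46 to 0.79), -0.07 (-0.23 to 0.09) and -0.07 (-0.22 to 0.09), and scaling by trimmed mean of M values (TMM) turned its day 14 ratio to 0.07.

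Socs3 (ENSMUSG00000053113) is a protein-coding gene on the minus strand of the same chromosome, at 117966079 to 117970047. It stood at 429 CPM (408 to 450) in sham microglia/macrophages and at 471 (457 to 487), 310 (302 to 319), 153 (149 to 156) and 149 (146 to 152) CPM at days 1, 3, 7 and 14. These levels rest on 1573, 3860, 5359, 7555 and 10366 UMIs. The log2 ratios to sham were 0.14 (0.05 to 0.22), -0.47 (-0.55 to -0.38), -1.49 (-1.57 to -1.41) and -1.53 (-1.60 to -1.45). Relative to the median of all genes they were 0.21, -0.10, -1.11 (-1.19 to -1.03) and -0.97 (-1.05 to -0.89). In microglia-like clusters alone Socs3 stood at -1.46 at day 7 and -1.38 (-1.45 to -1.30) at day 14, and Alkbh5 at -0.42 and -0.62.

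Socs3 levels of single cells went with a list of 19 immediate early and heat shock genes, which respond to tissue dissociation. With each microglia/macrophage thinned to 500 UMIs, these genes averaged 20.5 UMIs per cell in sham and 10.6, 8.09, 6.35 and 4.87 at days 1, 3, 7 and 14. Sham cells with 20 or more of them held 546 CPM of Socs3, and sham cells with 5 to 7 held 162 CPM. When sham cells were reweighted to each injured library's distribution of these UMIs, the Socs3 log2 ratios became 0.76 (0.60 to 0.93), 0.64 (0.40 to 0.87), -0.45 (-0.86 to -0.10) and 0.20 (-0.19 to 0.63). Within cells of 5 to 19 such UMIs they were 0.74, 0.56, -0.34 and 0.06. This reweighting was chosen after the data were seen, and the list also holds genes that injury can induce, such as Atf3 and Egr1.

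In cells thinned to 500 UMIs, 4.67% of sham microglia/macrophages had an Alkbh5 UMI, and 4.57%, 6.13%, 3.53% and 2.98% did so at days 1, 3, 7 and 14. A Socs3 UMI was found in 17.4% of thinned sham cells and in 20.1%, 14.3%, 5.92% and 7.99% of thinned injured cells. Without thinning, at median depths of 726 UMIs per cell in sham and 10465 at day 14, the Socs3 shares were 25.0% in sham, then 47.6%, 61.2%, 40.6% and 55.3%. The unthinned Alkbh5 shares were 7.38%, 17.0%, 35.8%, 38.0% and 47.1%. For comparison, 0.653% of thinned sham oligodendrocyte-like cells, at a median depth of 1516 UMIs, had a Socs3 UMI. At days 1, 3, 7 and 14, 5.11%, 4.16%, 0.571% and 0.879% did so. These shares cannot serve as a background of free RNA from microglia/macrophages. At day 1 oligodendrocyte-like cells held 19.01% of the microglia/macrophage CPM of Socs3, but between 1.26% and 2.02% of that of 9 abundant microglia genes. The Socs3 percentage was also the highest of these in every other library. No class served as background for Socs3, or for Alkbh5, which is widely expressed.

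**Figure D2:**
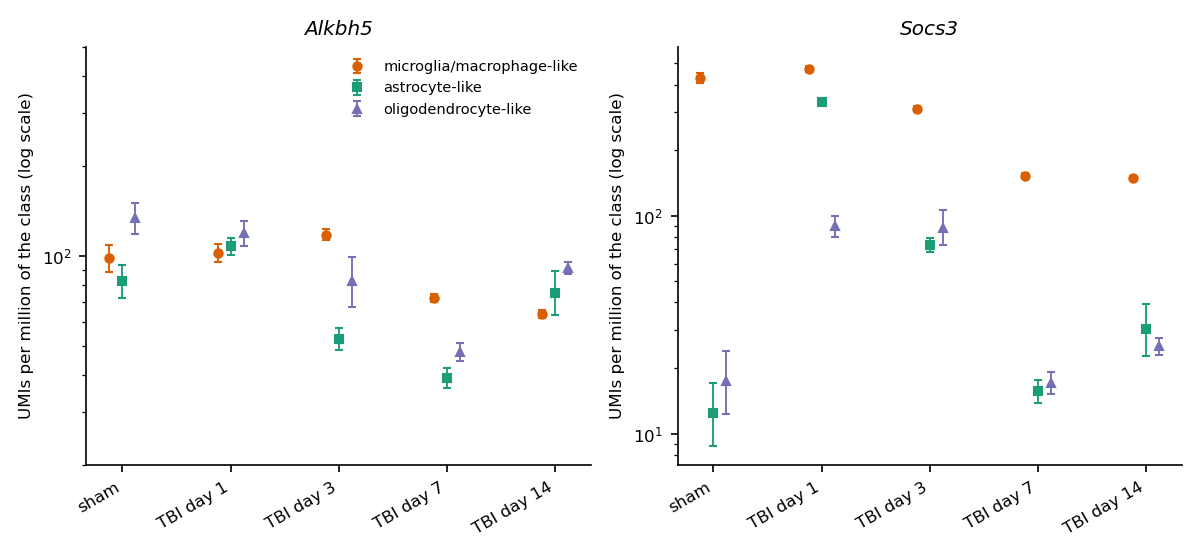
CPM of the class (vertical axes, log scale) of Alkbh5 and Socs3 in 3 cell classes of the 5 libraries, with exact 95% Poisson intervals for counting error only. Socs3 in microglia/macrophage-like cells runs from 429 in sham to 149 at day 14, and in astrocyte-like cells from 12.4 in sham to 334 at day 1.

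**Figure D3:**
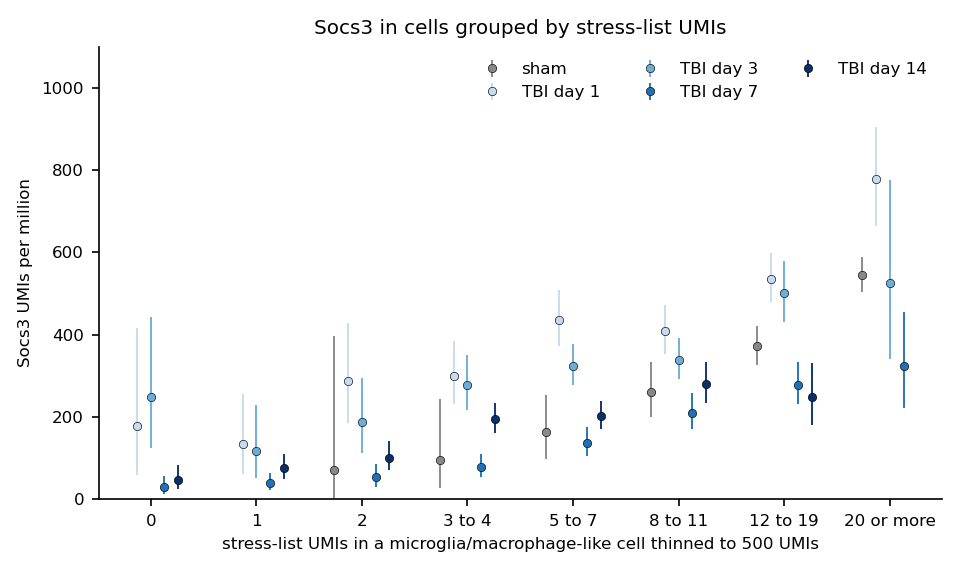
Socs3 CPM (vertical axis) in microglia/macrophage-like cells thinned to 500 UMIs and grouped by their UMIs from the immediate early and heat shock list (horizontal axis), by library, with exact 95% Poisson intervals. Groups with fewer than 20 cells of a library are not drawn, and sham cells hold 162 CPM of Socs3 at 5 to 7 list UMIs and 546 at 20 or more.

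Other m6A and JAK-STAT genes of the class were compared as fixed lists. Mettl3, the catalytic m6A writer, was lower in every injured library than in sham, and Stat3, the transcription factor that SOCS3 restrains, was higher at day 1. Mettl3 stood at 52.6 CPM in sham and 31.3, 10.5, 14.1 and 9.80 CPM after injury, or log2 ratios of -0.75, -2.33, -1.90 and -2.42. Its partner Mettl14 gave -0.21, -0.75, -0.86 and -1.10, and Fto, the other m6A eraser, 0.29, -0.74, -0.40 and -0.48. Stat3 stood at 87.5 CPM in sham and 208, 105, 92.9 and 61.2 CPM after injury.

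The 2 erasers had median log2 ratios of 0.18, -0.24, -0.42 and -0.55 at days 1, 3, 7 and 14, with TMM scaling turning day 3 and day 14 to 0.14. Of the 2, only Alkbh5 reached 50 CPM at day 3, where it stood at 0.26. The 9 writers gave -0.09 (0.09 with 1000 UMIs per cell), -0.55, -0.72 and -0.91, with 4 at least 2-fold lower at day 14, among them Rbm15b at -1.41. Wtap stood at -1.04 at day 7 and Mettl16 at -1.11 at day 3. The 7 measured readers gave 0.02 (-0.01 by marker score), -0.37 (0.01 under TMM), -0.51 and -0.81, with Ythdf3, Ythdf1, Ythdc1 and Hnrnpa2b1 at -1.03, -1.07, -0.82 and -0.75 at day 14. Relative to the median of all genes, the day 14 medians were 0.01 for erasers, -0.35 for writers and -0.25 for readers. Their percentiles among 10000 random lists of like expression were 47.9, 13.1 and 17.5.

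The 6 measured SOCS genes had medians of 0.10, -0.37, -0.22 and -0.84, which TMM scaling turned to 0.11 at day 3 (0.01 over the same 6 genes) and 0.19 at day 7. Socs5 stood at -2.23 at day 3, Socs1 at -1.08 at day 14, and Socs6 at -0.51 at day 14 (0.19 under TMM). Socs3 was the only member of at least 50 CPM at days 7 and 14. The 13 JAK-STAT and gp130 receptor genes gave -0.05 (0.03 under TMM), -1.04, -0.45 (0.01 under TMM, -0.04 over the same 13 genes) and -0.69 (0.01 under TMM). At day 3, 7 of them were at least 2-fold lower than in sham, including Tyk2 at -1.46 and the gp130 gene Il6st at -1.28. Il6ra, the interleukin-6 receptor, stood at 85.2 CPM at day 14 against 265.

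At day 1, the inflammatory and glycolysis lists had medians above sham in microglia/macrophages, and homeostatic microglia genes a median below it. Msr1, a macrophage scavenger receptor, stood at 353 CPM against 1.36 in sham, a log2 ratio of 8.02 (6.79 to 9.64). Fn1, encoding fibronectin, stood at 239 against 2.45 CPM (log2 6.61, 5.68 to 7.74), and Ccl7, a monocyte chemoattractant, at 364 against 6.54 CPM (log2 5.80, 5.22 to 6.44). Another class of the day 1 library held 1132 CPM of Fn1. P2ry12, the purinergic receptor of resting microglia, stood at 304 against 2334 CPM (log2 -2.94, -3.01 to -2.88).

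Further genes named as higher at day 1 were Adam8 at 157 against 1.91 CPM, Lpl (lipoprotein lipase) at 582 against 16.1, Ch25h (cholesterol 25-hydroxylase) at 72.8 against 1.09 and Dab2 at 428 against 13.1. Cd72, Lgals1 (galectin-1), Pf4, Slc39a14 and G530011O06Rik were between 19.9-fold and 28.4-fold higher than in sham. Adam8, Ch25h, Lgals1 and Slc39a14 each stood higher in another class of the day 1 library, at 319, 163, 274 and 241 CPM. Those named as lower included Thrsp at 6.35 against 80.4 CPM, the fructose transporter gene Slc2a5 at 30.8 against 243, Il7r at 8.55 against 68.7 and Crybb1 at 62.9 against 426. Gimap6, Il16 and Ypel3 were 9.51-fold, 7.96-fold and 7.29-fold lower. Requiring 1000 UMIs per cell, which leaves fewer sham cells, moved the log2 ratios of Fn1, Adam8, Lpl, Ch25h and Lgals1 to 5.06, 5.43, 4.46, 4.73 and 2.84. Fn1 stood at 7.63 and Lgals1 at 5.19 in microglia-like clusters alone.

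Among the fixed lists at day 1, the inflammatory cytokine and NF-kB list had a median log2 ratio of 1.11, with 10 of 20 measured genes at least 2-fold higher and 0 lower. Glycolysis stood at 1.18, with 7 of 12 genes at least 2-fold higher, among them Pkm at 4.36-fold, Pgk1 at 4.25-fold and Tpi1 at 3.16-fold. Disease-associated microglia genes stood at 1.18 (0.55 with 1000 UMIs per cell), cell cycle genes at 1.15 and interferon response genes at 0.48. Alternative activation stood at 1.46, and at 0.43 in microglia-like clusters alone and 0.56 over members of at least 50 CPM. Homeostatic microglia genes stood at -1.13, with 8 of 15 at least 2-fold lower. Cholesterol efflux and lipid storage stood at 0.77, complement at 0.19 with the receptor gene C5ar1 at 11.1-fold, and cholesterol synthesis at -0.25. MHC class II stood at -0.32 and turned to 0.28 at Leiden resolution 2 and 0.33 as a mean over cells. The heat shock and immediate early list stood at -0.83.

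At day 3, the cell cycle list had a median above sham and the homeostatic list one below it, and monocyte/macrophage-like cells were 24.6% of the class. Arg1, encoding the arginine-consuming arginase, stood at 321 CPM against 0 UMIs in sham, at least 393-fold higher against a floor of 3 UMIs. Lgals3, encoding galectin-3, stood at 1136 against 14.7 CPM (log2 6.27, 5.89 to 6.68). Mki67, a marker of dividing cells, stood at 119 against 4.36 CPM (log2 4.77, 4.07 to 5.58). Cx3cr1, the microglial fractalkine receptor, stood at 622 against 6137 CPM (log2 -3.30, -3.34 to -3.27).

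Genes named as higher at day 3 included the chemokine Pf4 at 811 against 2.18 CPM, Lgals1 at 843 against 5.72, Ecm1 at 193 against 2.18 and Lilr4b at 198 against 2.73. Lgals1 and Lilr4b each stood higher in another class of that library, at 2971 and 498 CPM. Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rested on 2 sham UMIs, with a log2 ratio of 9.12 (7.27 to 12.16). Acp5 and the fatty acid scavenger Cd36 rested on 1 sham UMI each, with log2 ratios of 8.00 (5.52 to 13.30) and 7.71 (5.23 to 13.01). Msr1 stood at 98.2 CPM, Gm10076 at 97.1-fold its sham level, and the immunoglobulin gene Igha at 71.8 CPM against 0, with 98.2% of its 1241 UMIs in 10 cells. In microglia-like clusters alone, Arg1 stood at 2.26, Pf4 at 4.06, Gpnmb at 5.23, Acp5 at 4.44, Ecm1 at 3.68, Cd36 at 5.94, Lgals1 at 6.44, Lgals3 at 5.28, Lilr4b at 7.33 and Msr1 at 5.52 on the log2 scale. There Hspa1b and Hspa1a stood at -5.05 and -4.50, Chil3 at 4.12, Cxcl2 at 3.93 and Plin2 at 3.41.

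With 1000 UMIs per cell, the day 3 log2 ratios of Arg1, Gpnmb, Lgals1, Igha, Lgals3, Acp5, Ecm1, Lilr4b and Cd36 were each lower, from 4.38 for Cd36 to 6.87 for Arg1, and Igha was 0.80 when each cell was named by its own markers. Arg1 was 7.90 as a mean over cells. Genes named as lower at day 3 were Gal3st4, a sulfotransferase gene, at 0.868 against 59.7 CPM, and the heat shock genes Hspa1b, Hspa1a and Hsph1 at 22.0-fold, 14.8-fold and 16.3-fold lower. Hspa1a and Hspa1b are near-identical, so the split of UMIs between them is uncertain. The others, BC037034, Asb2, Col27a1 and Klhdc8b, were 24.4-fold, 26.3-fold, 20.6-fold and 21.3-fold lower.

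Cell cycle genes had a median of 4.0 at day 3, with 15 of 18 at least 2-fold higher, among them Birc5 at 64.1-fold, Ube2c at 58.9-fold and Cenpa at 24.1-fold. In microglia-like clusters alone the cell cycle median was 4.25, with 18 of 20 higher. It was 3.21 with 1000 UMIs per cell, where Birc5, Ube2c and Mki67 stood at 4.99, 4.87 and 3.44 on the log2 scale, and 2.95 over members of at least 50 CPM. Mki67 stood at 5.43 as a mean over cells. Homeostatic microglia genes stood at -2.25, with 14 of 15 at least 2-fold lower, including Slc2a5 at 20.9 against 243 CPM and P2ry13 at 41.2 against 413. In microglia-like clusters alone that median was -1.82, with 11 of 15 at least 2-fold lower. Alternative activation stood at 1.69, with Chil3 at 256 against 2.45 CPM (log2 5.77 with 1000 UMIs per cell, 7.33 as a mean over cells), and at 0.28 over 6 measured genes in microglia-like clusters alone (1.15 over the same 9 genes). MHC class II, which presents antigen to T cells, stood at 3.40 over 6 measured genes and at 2.26 with 1000 UMIs per cell. In microglia-like clusters alone it stood at -0.24 over the 4 genes measured there, without H2-Aa and H2-Eb1, and at 0.24 over the same 6 genes.

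Disease-associated microglia genes stood at 1.74 at day 3, with 16 of 23 at least 2-fold higher. The inflammatory list stood at 0.44, with Cxcl2, a neutrophil chemoattractant, at 703 against 27.5 CPM (log2 3.91 with 1000 UMIs per cell). Interferon response stood at 0.56, complement at 0.19 and glycolysis at 0.61, with Pfkl at -1.87. Cholesterol efflux and lipid storage stood at 1.10, with the lipid droplet gene Plin2 at 16.2-fold. Cholesterol synthesis stood at -1.13, with Fdft1 at -2.27, and the heat shock and immediate early list at -1.35.

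At day 7, the cholesterol efflux and lipid storage list and the interferon response list had medians above sham in microglia/macrophages. Apoe, encoding the lipid carrier apolipoprotein E, stood at 65622 against 1388 CPM (log2 5.56, 5.52 to 5.60). Gpnmb stood at 549 CPM (log2 9.98, 8.12 to 13.02). Rsad2, which encodes the antiviral protein viperin, stood at 115 against 7.09 CPM (log2 4.02, 3.47 to 4.64). The interferon response list had a median of 1.65, with 14 of 20 genes at least 2-fold higher, including Oasl1 at 22.1-fold and Ifit2 at a log2 ratio of 3.46.

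Genes named as higher at day 7 also included the growth factor gene Igf1 at 124 against 1.91 CPM, Ms4a7 at 165 against 1.36 and Cst7 (cystatin F) at 253 against 10.6. Apoc1 and Apoc4 rested on 3 and 1 sham UMIs, with log2 ratios of 8.76 (7.22 to 11.04) and 8.33 (5.85 to 13.64). Cd5l and Gpx3 had 0 sham UMIs and were at least 74.5-fold and 71.5-fold higher. Lgals1 and Gm10076 were 24.3-fold and 33.5-fold higher, and Gm42418, which overlaps ribosomal RNA sequence, stood at 20067 against 687 CPM. Lgals1 and Gm42418 each stood higher in another class of the day 7 library, at 556 and 57437 CPM. With 1000 UMIs per cell the log2 ratios of Gpnmb, Cd5l, Gpx3, Apoc4, Cst7, Lgals1, Rsad2 and Igf1 became 7.67, 4.47, 4.43, 4.97, 3.65, 2.84, 3.13 and 7.06. As a mean over cells, Cd5l, Gpx3 and Igf1 stood at 5.23, 5.41 and 5.43, and with all other cells as the naming reference Cd5l and Igf1 stood at 4.79 and 5.37. Gpnmb, Gpx3 and Ms4a7 stood at 8.08, 5.48 and 7.63 in microglia-like clusters alone.

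Genes named as lower at day 7 were Hspa1b and Hspa1a, at 36.6-fold and 15.9-fold lower than in sham, Gal3st4 at 31.7-fold and AC102496.1 at 25.9-fold. Fam71a, Klhdc8b and Mir142hg were 13.6-fold, 12.7-fold and 11.4-fold lower. The small nuclear RNA Rn7sk stood at 22.4 against 234 CPM, or -3.38 on the log2 scale and -2.76 with 1000 UMIs per cell.

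Disease-associated microglia genes had a median of 2.14 at day 7, with 17 of 23 at least 2-fold higher. Cholesterol efflux and lipid storage stood at 1.26, with 7 of 11 higher, and cholesterol synthesis at -1.02, with 5 of 9 lower, including Msmo1 at -2.00. Homeostatic microglia genes stood at -1.22, with 10 of 15 lower. The inflammatory list stood at -0.22, which turned to 0.19 under TMM scaling and 0.14 over the 17 members of at least 50 CPM. Alternative activation stood at -0.01 (0.40 under TMM), glycolysis at 0.38 and complement at 0.04 (-0.01 as a mean over cells). Cell cycle stood at 0.19 over 9 measured genes, and as a mean over cells at -0.25 over the 6 measured then and 0.13 over the same 9. MHC class II stood at 0.88, and between 0.26 (4 members of at least 50 CPM) and 2.18 over the other settings that moved it by more than 1.5 times. The heat shock and immediate early list stood at -2.20.

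At day 14, the MHC class II and disease-associated microglia lists had medians above sham in microglia/macrophages, with 4 of 6 and 17 of 23 genes at least 2-fold higher, and monocyte/macrophage-like cells were 21.8% of the class. Spp1, encoding osteopontin, stood at 12584 against 14.2 CPM (log2 9.79, 9.40 to 10.22). H2-Aa and H2-Eb1, chains of the MHC class II dimer, stood at 961 against 20.7 CPM (log2 5.54, 5.21 to 5.88) and 722 against 22.9 CPM. Cd74, the invariant chain, stood at 2338 against 95.4 CPM, and H2-Ab1 at 897 against 39.0. The MHC class II list had a median of 4.57, with H2-DMa at 237 against 226 CPM and H2-DMb1 at 110 against 76.0, and of 4.48 in microglia-like clusters alone.

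Microglia-like clusters held 1017 CPM of Cd74 at day 14, monocyte/macrophage-like cells 5903, oligodendrocyte-like cells 98.1 and the 274 astrocyte-like cells 725. At day 3 the microglia-like and monocyte/macrophage-like levels were 53.3 and 2832 CPM. With 1000 UMIs per cell, the day 14 log2 ratios of H2-Aa, H2-Eb1 and H2-Ab1 were 4.65, 4.08 and 3.92, and at Leiden resolution 2 they were 6.18, 5.69 and 5.20. H2-Aa and H2-Eb1 stood at 6.57 and 6.10 in microglia-like clusters alone and at 6.19 and 5.73 as a mean over cells, and H2-Aa at 6.14 by marker score.

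Several genes named as higher at day 14 had almost no sham UMIs. Gpnmb stood at 704 CPM on 2 sham UMIs (log2 10.33, 8.48 to 13.38), the chemokine Ccl8 at 387 on 1 (log2 10.47, 7.99 to 15.78), and Apoc1 and Apoc4 at 8.79 and 9.06 on the log2 scale on 3 and 1. Ms4a7 stood at 409 against 1.36 CPM, Saa3, a serum amyloid gene, at 309 against 1.91, and Pf4 at 243 against 2.18. Cxcl13, a B cell chemoattractant, stood at 79.0 CPM and was at least 96.6-fold higher, with 111 CPM in another class of that library. In microglia-like clusters alone the log2 ratios were 6.90 for Ccl8, 4.81 for Pf4 and 9.20 for Gpnmb. With 1000 UMIs per cell they were 7.08 for Ccl8, 7.95 for Gpnmb, 8.48 for Spp1, 5.66 for Apoc4, 4.78 for Cxcl13 and 8.34 for Saa3. Ccl8 was 9.53 as a mean over cells, and naming against all other cells gave 8.04 for Spp1, 8.01 for Apoc1 and 8.42 for Apoc4.

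The immunoglobulin genes Ighg2b, Ighg1, Igha and Jchain, made by plasma cells, stood at 297, 97.2, 94.1 and 61.6 CPM in day 14 microglia/macrophages. Between 58.6% and 85.6% of their UMIs lay in 10 cells each, and an unnamed cluster of the same library held 37654 CPM of Ighg2b. Their log2 ratios to sham, or lower bounds, lay between 6.23 and 10.09, and naming each cell by its own markers lowered them to 8.62, 4.03, 5.61 and 4.05. Genes named as lower at day 14 included Hspa1b at 9.17 against 2371 CPM, Rn7sk at 1.72 against 234, Hspa1a at 25.5 against 2659 and the transcription factor genes Klf4 at 35.8 against 803 and Klf2 at 86.3 against 1574. Hspa1b, Hspa1a, Klf4 and Klf2 belong to the heat shock and immediate early list, which was highest in sham and responds to dissociation. Gal3st4, Klhdc8b and Khdrbs3 were 30.4-fold, 28.2-fold and 23.6-fold lower. Hspa1b stood at -8.01 on the log2 scale, at -7.28 with 1000 UMIs per cell and at -7.37 at Leiden resolution 2. Hspa1a stood at -7.44 in microglia-like clusters alone, and Klhdc8b and Khdrbs3 at -4.21 and -3.93 as a mean over cells.

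Disease-associated microglia genes had a median of 2.55 at day 14, with Apoe at 75658 against 1388 CPM, and of 3.47 over members of at least 50 CPM. Interferon response stood at 1.51, with Zbp1 at 3.46. Cholesterol efflux and lipid storage stood at 1.25, with Pltp at 22.5-fold (log2 3.18 in microglia-like clusters alone), and cholesterol synthesis at -1.65, with Idi1 at -2.44 and Insig1 at -1.85. Complement stood at 0.73, with C4b at 23.5-fold, Cfp at 14.5-fold (log2 1.06 in microglia-like clusters alone) and C3 on 3 sham UMIs at 71.8-fold (24.6 to 348). With 1000 UMIs per cell C3 and C4b stood at 4.38 and 3.69 on the log2 scale, and C3 at 7.25 as a mean over cells. Homeostatic microglia genes stood at -1.75 (-1.36 in microglia-like clusters alone), and P2ry12 at 303 against 2334 CPM (log2 -2.36 as a mean over cells).

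The inflammatory list stood at -0.96 at day 14, with 10 of 20 genes at least 2-fold lower and 4 higher. Il6 was at 0.674 against 21.3 CPM and the T cell chemoattractant Ccl5 at 415 against 9.27 (log2 4.76 with 1000 UMIs per cell). Heat shock and immediate early UMIs averaged 20.5 per thinned cell in sham and 4.87 at day 14. The reweighting by these UMIs was not run for the inflammatory list, so a stress response of sham cells stays open for its lower values. Alternative activation stood at -0.29, with Igf1 at 218 against 1.91 CPM (log2 7.84 with 1000 UMIs per cell, 5.92 under the other naming), over 7 measured genes. It turned to 0.61 with 1000 UMIs per cell and 1.48 with all other cells as the naming reference, where 8 genes were measured, and to 3.50 under TMM, where 10 were. Over the same 7 genes these settings gave -0.22, -0.13 and 0.41. Glycolysis stood at 0.92, cell cycle at 0.61 (as a mean over cells -0.06 over 8 measured genes and 0.36 over the same 13) and the heat shock and immediate early list at -2.33. The median of all genes was -0.56 at day 14, and relative to it the inflammatory list stood at -0.40, MHC class II at 5.13, disease-associated microglia at 3.11 and homeostatic microglia at -1.19.

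Among the matched random lists, homeostatic microglia medians lay at percentiles of 0, 0, 0.10 and 0 at days 1, 3, 7 and 14, and disease-associated microglia medians at 100 in all 4 libraries. The heat shock and immediate early list lay at percentiles of 0.06, 0.03, 0 and 0, and the inflammatory list at 100, 97.6, 60.2 and 1.04. Microglia-like cells of each library fell mainly in a cluster of their own: cluster 0 held 4395 sham cells, cluster 3 held 3838 at day 1, cluster 8 held 2308 at day 3, cluster 1 held 4111 at day 7 and cluster 5 held 2975 at day 14. A cluster mostly of 1 library may be that library rather than a cell type.

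**Figure D4:**
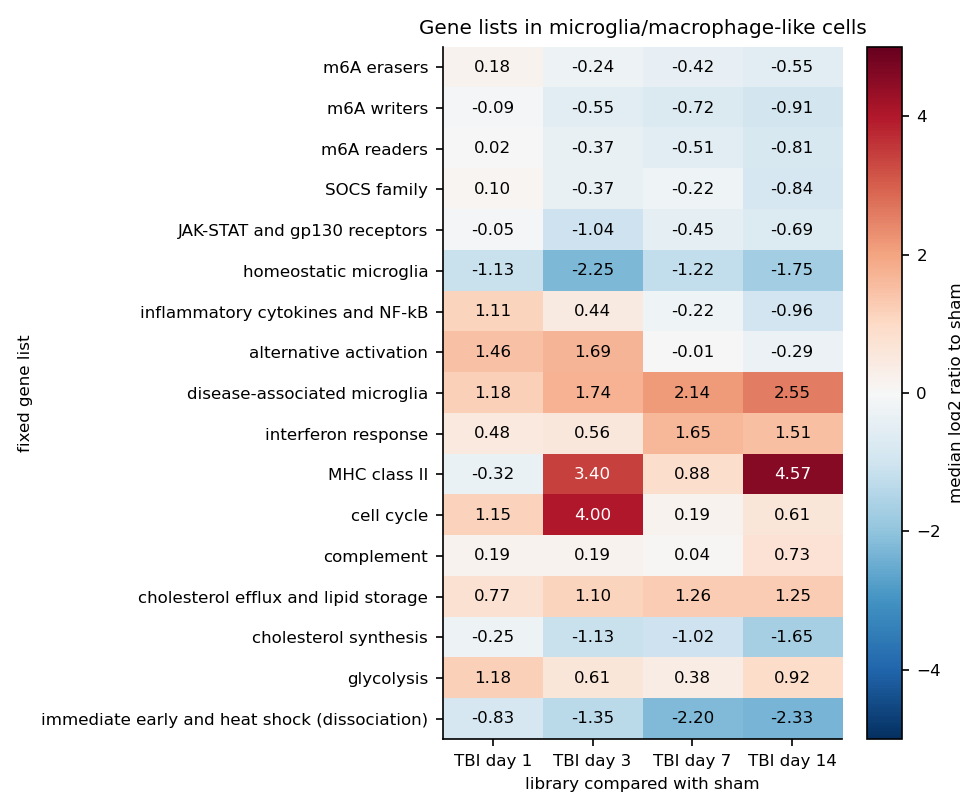
Median log2 ratio of CPM to sham (colour and printed value) of 17 fixed gene lists (vertical axis) in microglia/macrophage-like cells of each injured library (horizontal axis). MHC class II reads 3.40 at day 3 and 4.57 at day 14 and homeostatic microglia read below 0 in all 4 libraries, while TMM scaling turns the sign of the erasers (days 3 and 14), readers (day 3), SOCS (days 3 and 7), JAK-STAT (days 1, 7 and 14), inflammatory (day 7) and alternative activation (days 7 and 14) values.

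**Figure D5:**
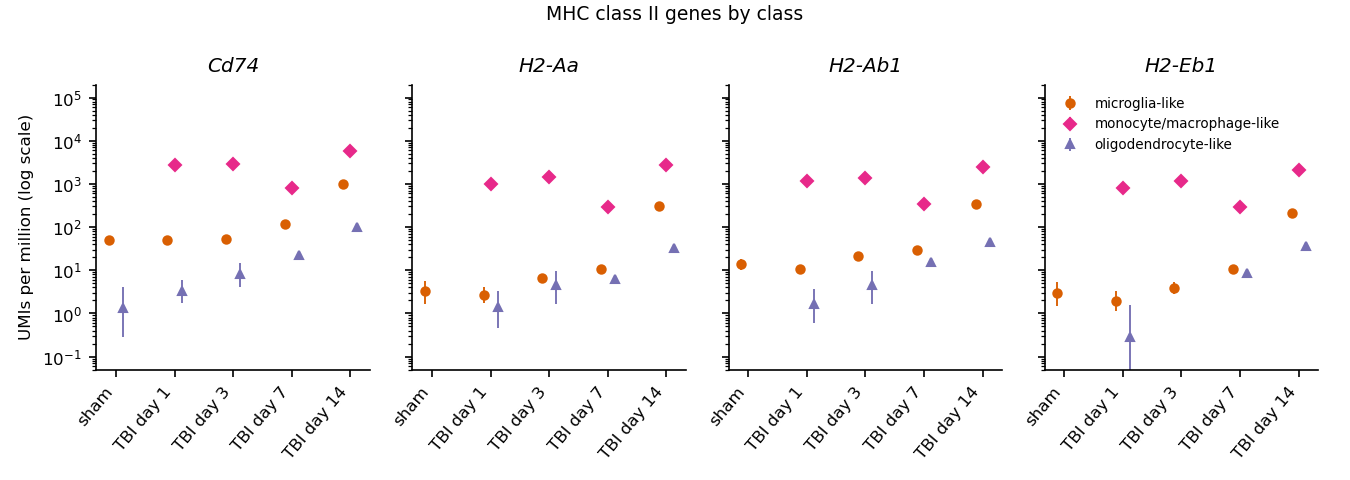
CPM (vertical axes, log scale) of the MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 in microglia-like, monocyte/macrophage-like and oligodendrocyte-like cells of the 5 libraries (horizontal axes), with exact 95% Poisson intervals. Cd74 in microglia-like cells reads 53.3 at day 3 and 1017 at day 14, and the 20 sham monocyte/macrophage-like cells and values of 0 are not drawn.

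Astrocyte-like cells were compared next, as injury-responsive glia. The reactive astrocyte list had a median above sham in every injured library, and Socs3 was 26.9-fold higher at day 1. Socs3 stood at 12.4 CPM (8.78 to 17.0) in sham astrocyte-like cells and at 334 (321 to 347), 73.8, 15.7 and 30.2 CPM after injury. Its log2 ratios were 4.75 (4.29 to 5.25), 2.57 (2.10 to 3.08), 0.34 (-0.16 to 0.87) and 1.28 (0.66 to 1.92). Stat3 stood at 35.6 CPM in sham and 240, 147, 99.8 and 117 CPM after injury.

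Reactive astrocyte genes had medians of 6.19, 5.71, 3.63 and 4.89, with 16 of 18, 15 of 17, 12 of 14 and 19 of 19 measured genes at least 2-fold higher. Lcn2, encoding lipocalin-2, stood at 1002 CPM at day 1 against 0 sham UMIs, at least 1024-fold higher, and Ptx3, encoding pentraxin 3, at 694 against 1.31 CPM. Timp1, a metalloproteinase inhibitor gene, was at least 622-fold higher at day 3, and the complement gene C3 at least 345-fold higher at day 14. The 274 astrocyte-like cells of day 14 also held 725 CPM of Cd74, against 1.31 in sham. They held between 4.83% and 7.58% of the microglia/macrophage CPM of 9 abundant microglia genes, against 2.21% to 3.26% in sham. Whether RNA of immune cells adds to the day 14 values of astrocyte-like cells was not tested. Astrocyte homeostasis genes had medians of -0.87, -0.62, -0.60 and -0.83, with 5, 5, 4 and 4 of 14 at least 2-fold lower and Slc6a11, a GABA transporter gene, at 168 against 1269 CPM at day 3. Ntsr2, Slc7a10 and Gja1, a gap junction gene, were 4.37-fold, 3.62-fold and 2.82-fold lower at day 3.

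The SOCS list of astrocyte-like cells stood at 1.59, 0.25, 0.06 and 0.57, with Socs1, Socs5 and Socs4 at 9.82-fold, 3.87-fold and 2.36-fold at day 1. The m6A erasers stood at 0.08, -0.52, -0.69 and -0.21, the writers at -0.10, -0.56, -0.24 and -0.12, and the readers at 0.53, -0.37, -0.31 and -0.18. Alkbh5 itself stood at 82.3 CPM in sham and 108, 52.8, 39.0 and 75.5 CPM after injury. Mettl3 stood at 60.1 CPM in sham and 27.7, 12.2, 13.9 and 12.9 CPM, Wtap was 2.34-fold lower at day 7, Hnrnpa2b1 2.74-fold lower at day 3 and Hnrnpc 2.26-fold higher at day 14. Medians of all genes in this class were -0.06, -0.13, -0.14 and 0.13. Cluster 11 (1971 cells) and cluster 6 (2030) held most sham astrocyte-like cells, cluster 4 (3323) those of day 1, cluster 17 (1215) and cluster 15 (818) those of day 3 and cluster 12 (1454) those of day 7.

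Oligodendrocyte-like cells, the myelin-forming glia, had medians above sham for injury-response genes and below it for myelin genes, which were also markers that named the class. Myelin genes had medians of -0.53, -0.75, -0.39 and -0.24, with 1, 4, 1 and 0 of 11 at least 2-fold lower and percentiles of 1.95, 4.37, 25.8 and 5.77 among random lists. Named members were Opalin at 207 against 1463 CPM at day 3, Ugt8a 7.04-fold lower at day 3, and Mog 2.07-fold lower at day 1. The injury list had medians of 0.70, 1.48, 1.08 and 1.81, with 5, 9, 6 and 8 of 12 genes at least 2-fold higher and 1, 0, 1 and 0 lower. Serpina3n, a protease inhibitor gene, stood at 1401 CPM at day 3 against 0 sham UMIs, at least 1021-fold higher, and the cell cycle inhibitor gene Cdkn1a at 992 against 13.3 CPM. The complement gene C4b stood at 1465 against 5.49 CPM at day 14 and the MHC class I gene H2-D1 at 931 against 51.2.

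Socs3 in oligodendrocyte-like cells stood at 17.4 CPM in sham and 89.6, 88.3, 17.1 and 25.1 CPM after injury, and Alkbh5 at 134, then 119, 82.3, 47.8 and 91.0 CPM. The SOCS list stood at 1.27, 1.47, -0.02 and 0.53, with Socs6 at 4.78-fold and Socs5 at 1.51 against 30.7 CPM at day 3 and Socs4 at 2.51-fold at day 1. The erasers stood at -0.23, -0.71, -1.20 and -0.50, the writers at 0.34, -0.06, -0.04 and 0.14 and the readers at 0.50, 0.15, 0.20 and 0.31. Mettl3 stood at 28.4 CPM in sham and 8.30 CPM at day 3. Cluster 7 held 970 of the sham and 1002 of the day 1 cells, and cluster 2 held 1541 at day 7 and 1872 at day 14.

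Endothelial-like cells, which line blood vessels, numbered 76 in sham and 64, 67, 372 and 64 after injury, so their values rest on few UMIs. Adhesion and activation genes had medians of 1.80, 1.98, 0.32 and 0.42 at days 1, 3, 7 and 14, and tip cell and angiogenesis genes 2.37, 1.26, 0.20 and 0.22. At day 3 Lcn2 stood at 693 against 38.0 CPM, and Lrg1 and Ch25h, with 0 sham UMIs, were at least 14.8-fold and 9.21-fold higher, while Upp1 was at least 2.59-fold higher at day 1. At day 1 the basement membrane collagen gene Col4a2 stood at 2204 against 257 CPM, Apold1 was 5.76-fold higher, Angpt2 at least 4.67-fold, and Trp53i11, on 1 sham UMI, had a log2 ratio of 4.77 (2.19 to 10.11).

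Blood-brain barrier genes of endothelial-like cells had medians of -0.15, -0.41, 0.25 and -0.71, with the glucose transporter gene Slc2a1 2.86-fold higher and Ctnnb1 2.86-fold lower at day 3, and Abcb1a and Mfsd2a at -1.35 and -1.42 at day 14. Socs3 stood at 19.02 CPM on 2 sham UMIs and at 126 CPM at day 1, a ratio of 6.61 (1.57 to 59.0). The SOCS list stood at 0.05, 0.47, 0.07 and -0.17, the erasers at 1.11, 0.19, 0.29 and 0.24, the writers at -0.49, -0.11, -0.39 and -0.29 and the readers at 0.32, -0.47, -0.18 and -0.04. Alkbh5 stood at 171 CPM in sham and 88.9 CPM at day 7.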

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

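Chosen after the results were seen were the tests against the median of all genes, the test of microglia/macrophage RNA in astrocyte-like cells and the bounds for microglia-like clusters alone, a setting fixed beforehand, while the reweighting of sham cells by heat shock and immediate early UMIs was added after the data were seen but, like the day 14 comparison of MHC class II with oligodendrocyte-like cells, had its bounds written before its result.

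Socs3 in microglia/macrophages stood 0.14 above sham at day 1 on the log2 scale and at -1.53 at day 14, opposite directions that were not tested against each other. Cells named monocyte/macrophage-like are excluded as the whole cause, since microglia-like clusters alone stood at -1.38 at day 14. Monocyte-derived cells with microglia-like markers would sit in those clusters and are not excluded. A general loss of counts to abundant genes is excluded as the whole cause, since Socs3 stood at -0.97 relative to the median of all genes. Stress of sham cells during dissociation stays a candidate explanation: with sham cells reweighted to the injured libraries' heat shock and immediate early UMIs, the day 14 ratio was 0.20 (-0.19 to 0.63). At day 7 the reweighted ratio stayed below 0, at -0.45 (-0.86 to -0.10), and in sham 131 cells with 6 Socs3 UMIs stood for the injured cells with fewer than 5 such UMIs. A lower Socs3 level with time after injury remains open and untested, because SOCS3 and the list can both respond to injury.

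In astrocyte-like cells Socs3 stood at 2.57 at day 3 while microglia/macrophages stood at -0.47, a difference that was not tested. The microglia/macrophage ratio turned to 0.64 and 0.56 under the reweightings. These were not run for astrocyte-like cells, so whether the directions differ under them was not examined. Free RNA or doublets from microglia/macrophages are argued against: at day 1 astrocyte-like cells held 70.8% of the microglia/macrophage CPM of Socs3, but between 1.41% and 2.33% of that of 9 abundant microglia genes. A loss of counts to abundant genes in the injured library could only lower Socs3, so the comparison with all genes could not bear on it. Such a loss in sham would raise most genes together, but the median of all genes was -0.06 at day 1. Relative to that median Socs3 stood at 4.81. Induction of Socs3 in astrocytes early after injury may account for the pattern, as a hypothesis found and tested on the same data, and a difference between these libraries that no replicate can show stays open.

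MHC class II in microglia/macrophages stood at -0.32 at day 1 (0.28 at Leiden resolution 2 and 0.33 as a mean over cells), 3.40 at day 3 and 4.57 at day 14, with no test between them. At day 3 the list stood at -0.24 in microglia-like clusters alone over the 4 genes measured there, and at 0.24 over the 6 genes behind its 3.40 in the whole class, so monocyte-derived cells joining the class may account for the day 3 level. At day 14 it stood at 4.48 in those clusters, so cells named monocyte/macrophage-like are not the whole cause there. Monocyte-derived cells with microglia-like markers would sit in those clusters, so this value cannot exclude them. Free RNA at one level in all cells is argued against, because microglia-like CPM exceeded oligodendrocyte-like CPM by a median of 3.30 on the log2 scale. Droplets that hold a microglial and a monocyte-derived cell stay open, since the 274 astrocyte-like cells of that library held as much H2-Aa and H2-Eb1 as microglia-like cells or more (322 against 313 and 250 against 207 CPM) and 725 against 1017 CPM of Cd74, and a response of microglia to injury stays open as untested.

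Alkbh5 in microglia/macrophages stood at 0.26 at day 3 and -0.62 at day 14, a difference that was not tested, and the day 14 value was 0.07 under TMM and -0.07 (-0.22 to 0.09) relative to the median of all genes. The m6A eraser list stood at 0.18 at day 1 and -0.55 at day 14, also untested, with 0.14 under TMM and 0.01 relative to that median at day 14. Inflammatory cytokine and NF-kB genes stood at 1.11 at day 1 and -0.96 at day 14, with no test of the difference. The reweighting by heat shock and immediate early UMIs was not run for them, so stress of sham cells during dissociation stays open. Alternative activation genes stood at 1.69 at day 3 (0.28 in microglia-like clusters alone) and -0.29 at day 14 (0.61 with 1000 UMIs per cell, 1.48 with the other naming reference and 3.50 under TMM, each over more measured genes), again not tested.

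In data outside the comparisons, 12.7% of day 7 barcodes had over 20% mitochondrial UMIs, against 0% in sham. Erythrocyte-like cells made up 6.96% of day 7 cells, choroid plexus-like cells 1.75% of day 3 cells and ependymal-like cells 0.709% of day 1 cells, where sham held 0 cells of each, which allows a share of up to 0.0293%. A difference between sham and injury site samples in the tissue taken was not tested. An unnamed cluster rich in immunoglobulin RNA made up 5.09% of day 14 cells and 0.0390% of sham cells.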

How the results depend on the processing

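Of the alternatives, the naming reference, the day 1 library in place of sham, the shares without classes scarce in sham and the heat shock reweighting were chosen after the data were seen. No paired analysis was possible because each group holds 1 library. Depth limits the sham side most, where 1 UMI is worth 0.273 CPM and 0 UMIs allow up to 0.818 CPM in microglia/macrophages.

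Of 47 alternative values of the Alkbh5 ratios, 46 kept their sign and 40 stayed within the counting interval, and for Socs3 43 of 47 and 26 of 47 did so. Of 677 values of list medians 644 kept their sign, and 20 of the others had a main interval that excludes 0. Within the counting interval lay 499 of the 677. Of 1197 values of named genes 1196 kept their sign and 950 stayed within the counting interval. These genes were picked for bounds far from 0, so their kept signs say little about how robust the ratios are. The cause was not tested for any change below, except where a setting acts by its own construction.

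The microglia/macrophage share in sham was 30.8% with 1000 UMIs per cell, 38.7% with doublets kept, 40.2% by marker score and 45.0% without the classes scarce in sham. At day 1 these gave 36.8%, 31.6%, 30.6% and 39.8%, with 33.5% at Leiden resolution 2. At day 3 they gave 44.4%, 39.8%, 38.3% and 51.0%. At day 7 the share was 65.5% with at most 10% mitochondrial UMIs, 41.9% with doublets kept, 44.3% at resolution 2, 47.6% by marker score, 46.4% with the other naming reference and 53.7% without the scarce classes. At day 14 it was 52.3% with 1000 UMIs, 47.0% with doublets kept, 51.0% at resolution 2, 48.5% by marker score, 40.8% with the other naming reference and 52.0% without the scarce classes. Leaving out classes raises a share by construction.

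Scaling by TMM raised every gene's ratio to sham by the same amount within a library, by construction of its factors, and also changed which list members reached 10 CPM. Alkbh5 became 0.64 at day 3, -0.034 at day 7 and 0.070 at day 14, where its sign turned. Socs3 became 0.22, -0.085, -1.08 and -0.83. TMM turned 11 list medians: erasers (day 3 and day 14, 0.14 each), readers (day 3, 0.012), SOCS (0.11 at day 3, or 0.015 over the reported members, and 0.19 at day 7), JAK-STAT (0.034 at day 1, 0.013 at day 7, or -0.037 over the reported members, and 0.0077 at day 14), inflammatory genes (day 7, 0.19) and alternative activation (0.40 at day 7, and 3.50 at day 14, or 0.41 over the reported members). It also turned the ratio of Socs6 at day 14 (0.19).

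Under the heat shock reweighting Socs3 was 0.76, 0.64, -0.45 and 0.20 at days 1, 3, 7 and 14, which turned days 3 and 14. In cells with 5 to 19 such UMIs it was 0.74, 0.56, -0.34 and 0.062, again turning days 3 and 14. Alkbh5 was -0.64 at day 7 with all cells, and 0.67, -0.16 and -0.19 at days 3, 7 and 14 in the narrower range. As a mean over cells Socs3 was -0.32, -1.63 and -1.37 at days 3, 7 and 14, and against the day 1 library -0.60, -1.62 and -1.66. In microglia-like clusters alone it was -0.30 at day 3 and -1.38 at day 14, and with the other naming reference -1.31 at day 14.

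Other list medians that changed sign, with a main interval that excludes 0, were MHC class II at day 1 (0.28 at resolution 2, 0.33 as a mean over cells) and complement at day 7 (-0.012 as a mean over cells). MHC class II at day 3 in microglia-like clusters alone (-0.24) was 0.24 over the reported members. Cell cycle at day 7 (-0.062 by marker score, -0.25 as a mean over cells) was 0.19 and 0.13 over the reported members, and at day 14 (-0.059 as a mean over cells) 0.36. Alternative activation at day 14 (0.61 with 1000 UMIs, 1.48 with the other naming reference) was -0.22 and -0.13 over the reported members. Over members of at least 50 CPM, erasers at day 3 (0.26, Alkbh5 alone) and inflammatory genes at day 7 (0.14) changed with the members counted, by construction. Of medians with a main interval that includes 0, JAK-STAT at day 1 also turned to 0.056 with 1000 UMIs, 0.0089 as a mean over cells and 0.098 at 50 CPM, writers at day 1 to 0.094 with 1000 UMIs, and readers at day 1 to -0.014 by marker score and -0.0063 with doublets kept. Alternative activation at day 7 turned to values between 0.0036 and 0.040 in 5 settings. The medians over reported members were added after the data were seen.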

Other observations

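Mettl3, the catalytic m6A writer, was lower than in sham in the injured libraries of several classes. In neural progenitor or neuroblast-like cells it stood at 63.1 CPM in sham and 38.8, 25.0, 21.6 and 32.8 CPM at days 1, 3, 7 and 14. The log2 ratios in microglia/macrophages relative to the median of all genes were -0.68, -1.96, -1.53 and -1.87, and in astrocyte-like cells -1.06, -2.17, -1.98 and -2.36. These values were picked out after they were seen and have no test. Every class was set against the same sham library, so the classes are not independent and do not repeat the result. A difference of that library cannot be told apart from injury here.

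Stat3 was higher than in sham in astrocyte-like cells of all 4 injured libraries, with log2 ratios of 2.76, 2.04, 1.49 and 1.72, and in oligodendrocyte-like cells, with 2.12, 0.77, 1.08 and 1.52. These ratios share the same sham library too. Neutrophil-like cells held 432, 620, 610 and 112 CPM of Socs3 at days 1, 3, 7 and 14. T or NK cell-like cells held 71.3, 74.5 and 35.5 CPM at days 3, 7 and 14. Monocyte/macrophage-like cells held 377, 225, 129 and 103 CPM from day 1 to day 14.

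Ttr, a choroid plexus transcript, stood at 0 CPM in sham microglia/macrophages and at 313, 132, 9.13 and 148 CPM in the injured libraries. Mbp, a myelin transcript, stood at 501, 126, 42.8, 186 and 119 CPM from sham to day 14, and the haemoglobin gene Hbb-bs at 406, 126, 0.289, 17.4 and 534 CPM. An unnamed cluster with fibroblast and mural cell genes made up 0.0293% of sham cells and 0.205%, 0.972%, 1.08% and 0.165% of the injured libraries.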
